A study of Mus musculus with 26 samples.

How the data were processed

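Expression was measured in 26 single mouse retinal amacrine cells, each on 1 Affymetrix Mouse 430 2.0 array. Per the labels' protocols, retinas were dissociated with papain, single fluorescent cells were picked by hand with a capillary pipette, their RNA was reverse transcribed from an oligo dT primer, and the cDNA was amplified by 35 cycles of PCR, biotin labelled and hybridised. The deposited values are linear signal intensity values per probe set, made by the authors with MAS5 per the submitters' processing notes; the version of that software is not given in the sources used here. In the values themselves the mean of each array, trimmed by 2% at each end, is 500, so the signals were taken as scaled to that mean and were not scaled again. The table holds no detection calls, and raw array images were not used here.

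All computing was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Of 45101 probe sets, 64 were controls, 34958 belonged to 1 gene, 932 to several genes and 9211, among them most of the controls, to no named gene. Probe sets were named through Entrez gene identifiers, which matched a current gene symbol for 34754 of them, and 0 symbols had to be updated. A gene with several probe sets was represented by the probe set with the highest mean log2 signal over all cells, which gave 18193 genes. Positions on the genome were not used. A gene was called detected in a cell at a signal of at least 2 times the trimmed mean, that is 1000. For differences, signals were raised to a floor of 0.4 times the trimmed mean (200, or 7.64 on the log2 scale) and log2 transformed. A difference against a group at the floor therefore understates the gap, and values at the floor have no order among themselves.

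Cells were grouped by age, reporter and stated culture as the labels give them. The labels name no animal, retina or culture, so each group counted as 1 sample. For that reason no p-value, standard error or count of changed genes was made from cells; SDs over cells describe spread, and exact Clopper-Pearson 95% intervals for shares of cells cover counting error only. The culture comparison was the difference of the 2 group means of log2 signals, and so was the reporter comparison. For age the difference was taken within each reporter and both were averaged. Lists of marker and pathway genes (34 lists, 417 genes written, 369 measured) were fixed before the data were examined, as were the comparisons, the rule for naming genes and most of the alternatives. Genes detected in at least 2 of the 26 cells (8570) entered, and 27 lists had at least 2 such members. Each list's median difference was placed among 10000 random lists of the same size, drawn from 20 bins of mean expression, and called outside their range below the 2.5th or above the 97.5th percentile. Partners of class markers were ranked by the phi coefficient of detection over 26 cells and set beside the best phi of other genes detected in as many cells. List genes without a named probe set were not analysed here.

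Genes were named by rule. For culture and reporter these were the 12 highest and the 12 lowest by difference of group medians among genes detected in at least 60% of the cells of the higher group. For age they were the 12 highest and the 12 lowest by the smaller of both reporters' differences, with the same sign in both. All genes of the amacrine class lists were covered by their count of cells, named from 3 cells upward or where a gene that defines a class was not detected. The 25 genes with the widest gap between cells with and without detection, among those detected in 3 to 13 cells, were named as subset markers, and the 5 best partners were named for each class marker detected in 4 to 20 cells. Within lists the members with the widest differences were named. Clone-type symbols were counted but not named. List genes of other cell types and cells with unusual values were named after their values were seen.

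The procedure was tested on simulated data for the culture comparison with 8570 genes. A planted log2 shift of 2 was recovered as 1.10 on average and a shift of 4 as 2.53, since the floor shortens differences. A planted list of 20 genes with a log2 shift of 4 reached the 100th percentile. Lists that were shorter or shifted by less were not planted, so their recovery was not tested. Of 100 random lists of 20 genes, 4 fell outside the central 95%, and a planted partner of Slc6a9 ranked first. Each gene was shuffled on its own, so the rate of 4 of 100 does not carry over to lists of co-detected genes. The planted partner differed from Slc6a9 in only 2 cells, so its rank checked the code alone. Alternatives covered detection at 1 and 4 times the trimmed mean, the highest or the median probe set per cell, floors of 0.1 and 1 times the trimmed mean, quantile normalization, scaling to the 75th percentile, no detection filter or detection in at least 5 cells, group medians, and leaving out each compared cell in turn. Leaving out cell B4 of the group with no culture stated, for counts and shares over all cells, was added after its values were seen.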

Results

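Gene expression was measured in 26 single mouse retinal amacrine cells, 1 cell per Affymetrix Mouse 430 2.0 array. Amacrine cells are inhibitory interneurons of the inner retina, and the labels state that the aim was to find markers of their many classes. Each cell had been picked by its green fluorescence after a reporter driven by the Ndrg4 or the Synapsin promoter (pNdrg4 or pSynapsin) was put into the retina by electroporation. The cells fell into 7 groups. There was 1 pSynapsin cell labelled E19 and there were 2 pNdrg4 cells labelled P4, all from retinas cultured for 4 days. At P5 there were 10 pNdrg4 cells with no culture stated, 5 pNdrg4 cells cultured for 5 days and 4 pSynapsin cells cultured for 5 days. At P8 there were 2 pNdrg4 and 2 pSynapsin cells, cultured for 8 days. Each sample was 1 cell and no label named an animal or a culture, so a group counted as 1 sample, no p-values were computed, and an SD given here is a spread over cells. The number of arrays limits the precision.

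The deposited signals had a trimmed mean of 500 on every array, and a gene was called detected at a signal of at least 1000. A median of 3253.5 genes of the 18193 measured was detected per cell, with a range of 1909 to 4180. The P5 pNdrg4 cells with no culture stated had a median of 2361.5 genes (range 1909 to 3513) and the cultured P5 pNdrg4 cells had 3256 (3049 to 3925). The P5 pSynapsin cells had 3472 (3291 to 3543). The P8 cells had 3382 and 4180 genes with pNdrg4 and 3467 and 3998 with pSynapsin, the P4 cells had 3418 and 2552, and the E19 cell had 2306. Over all cells, 124 genes were detected in all 26, 8021 in none and 1602 in 1 cell. Spearman correlations between pairs of cells, across 8570 genes that are not independent of each other, lay between 0.214 and 0.467.

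**Figure D1:**
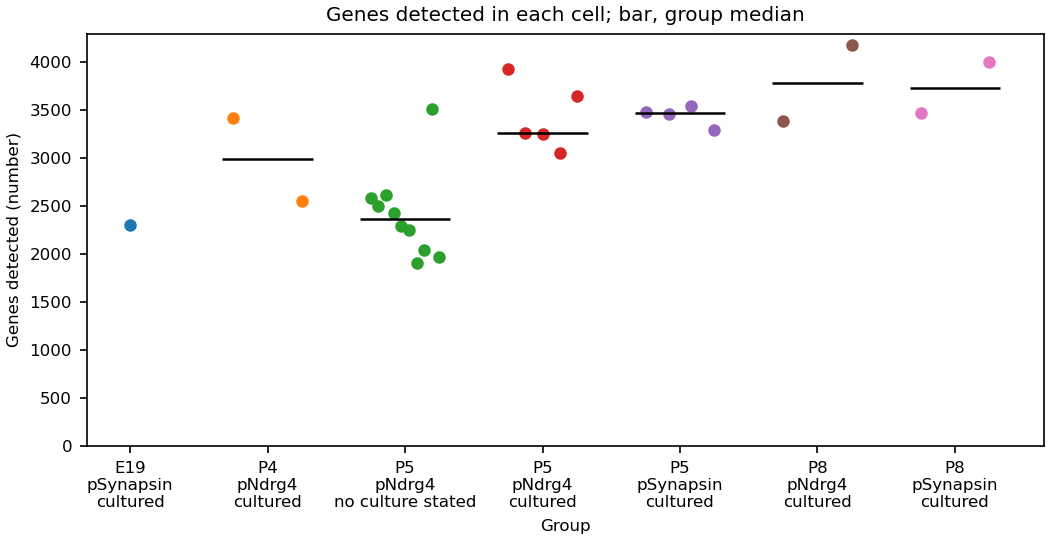
Number of genes detected per cell (signal of at least 1000, vertical axis) in the 7 groups, with 1 point per cell and a line at each group's median. The P5 pNdrg4 cells with no culture stated lie between 1909 and 3513 genes, with cell B4 the highest of that group, and the cultured P5 pNdrg4 cells lie between 3049 and 3925.

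The first question was which class markers the cells carried. Pax6, a transcription factor of the amacrine lineage, was detected in 26 of 26 cells (100%, Clopper-Pearson 95% interval 86.8 to 100, counting error only) with a median signal of 19864. Tfap2b was detected in 20 cells (76.9%, interval 56.4 to 91.0) and Tfap2a in 16 (61.5%, interval 40.6 to 79.8), and all 16 also had Tfap2b. Slc32a1, the vesicular transporter of GABA and glycine, was detected in 22 cells (84.6%, interval 65.1 to 95.6). The GABA-synthesising enzymes Gad1 and Gad2 were detected in 11 cells (42.3%, interval 23.4 to 63.1) and 14 cells (53.8%, interval 33.4 to 73.4), with median signals of 9423 and 4136 where detected. The glycine transporter gene Slc6a9 was detected in 14 cells with a median signal of 13612, and Slc6a5, the neuronal glycine transporter, in 5. Other transcription factors of the amacrine list marked smaller sets, among them Tcf4 (16 cells), Nhlh2 (13), Meis1 (12), Meis2 (12), Neurod1 (11), Barhl2 (10), Ebf3 (8), Ebf1 (7), Neurod4 (7), Neurod2 (6), Nr4a2 (5), Sox2 (4), Lhx9 (3) and Tfap2c (3). Among calcium-binding proteins, Cabp1 was detected in 13 cells, Necab1 in 10, Calb2 in 9, Hpca and Vsnl1 in 6 each, Necab2 in 4 and Ncald in 3.

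Gad1 and Slc6a9 were detected almost without overlap. Of the 26 cells, 23 (88.5%, interval 69.8 to 97.6) had exactly 1 of the pair, 1 cell had both (cell A6, no culture stated), and 2 had neither (cell A2, no culture stated, and cultured P5 pNdrg4 cell D6). The phi coefficient of their detection was -0.77, the lowest of all 7501 genes paired with Slc6a9. Of the genes detected in as many cells as Gad1, 96.3% had a lowest phi less low than this, and of those detected in as many cells as Slc6a9, 91.3% did. The split ran along the groups. Gad1 was detected in the E19 cell, both P4 cells, 7 of 10 P5 cells with no culture stated and 1 of 5 cultured P5 pNdrg4 cells, and in 0 of the 8 P5 pSynapsin and P8 cells. Slc6a9 was detected in 0 of the E19 and P4 cells, 3 of 10 cells with no culture stated, 3 of 5 cultured P5 pNdrg4 cells, and all 8 P5 pSynapsin and P8 cells. Gad2 showed no such separation from Slc6a9, with 7 cells having both, 7 each alone and 5 neither.

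Markers of several classes were not detected in any cell. Chat, Slc18a3 and Slc5a7 (acetylcholine synthesis and transport, starburst cells) and Th, Ddc and Slc6a3 (dopamine synthesis and uptake) were detected in 0 of 26 cells, as were the neuropeptide genes Vip and Sst, the calcium-binding protein genes Calb1 and Pvalb, and the early amacrine factors Ptf1a and Foxn4. Npy stayed below the detection level of 1000 but reached a signal of 804, with a median of 250.1. A count of 0 at this level, after amplification in which transcripts can be lost, does not show that a gene was absent. Other neuropeptide genes were strong in single cells. Tac1, which encodes substance P, reached a signal of 63686 in cell A7 (no culture stated) and was detected in no other cell, and Cartpt was detected in P4 cell A3 and cell A5 (no culture stated). The bombesin-family gene Nmb was detected in 4 cells. The AII list covers the glycinergic cell of the rod pathway. Dab1 was detected in 13 cells, Nfia in 6 and Gjd2 in 5, of the other list genes Calb2 in 9 and Prox1 in 2, and 4 cells (B1 with no culture stated, P5 pSynapsin E2, P8 pNdrg4 A1 and P8 pSynapsin B4) had Dab1, Nfia and Gjd2 together with Neurod2, which is not on that list, a combination chosen after its values were seen. In 9 of the 13 Dab1 cells Gjd2 was not detected. The same 4 cells had 4, 8, 7 and 10 rod photoreceptor genes detected. Ndrg4, whose promoter drove a reporter, was below the detection level in all 26 cells on both of its probe sets, and Syn1 was detected in 12 cells.

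**Figure D2:**
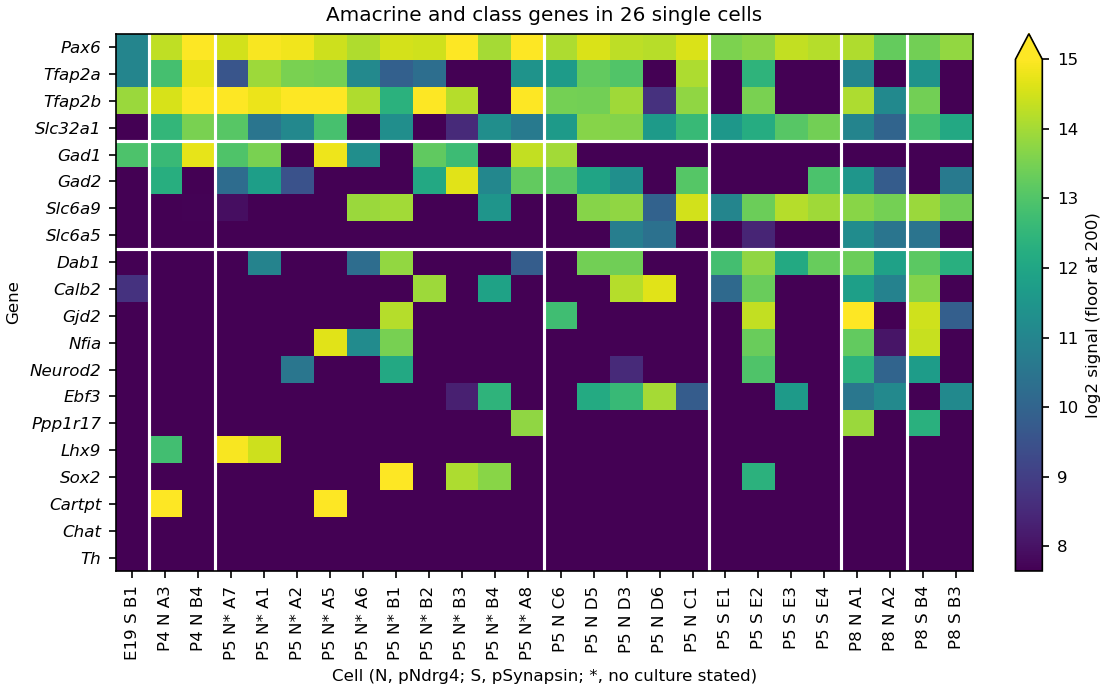
Signal of amacrine class markers (colour, log2 scale, with the floor of 200 as the lowest value) in each of the 26 cells, ordered by group along the horizontal axis, with 1 line per gene. Gad1 is detected in 11 cells and Slc6a9 in 14, with 1 cell holding both, and the cholinergic and dopaminergic genes Chat and Th stay below detection in all 26.

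The culture comparison set the 5 cultured P5 pNdrg4 cells against the 10 P5 pNdrg4 cells with no culture stated, and all differences are in log2 units, cultured minus none stated, of group means over cells. Class markers differed too, with Gad1 detected in 1 of 5 and 7 of 10 cells and Slc6a9 in 3 of 5 and 3 of 10. Culture and the mix of classes were therefore not separate. Kcnip1, the best match of Gad1 (phi 0.77), and Slc6a9, Lamp5 and Lhfp, the furthest from it (phi -0.77), are among the genes below. The cultured cells had higher Sphkap, an anchoring protein of protein kinase A, by 5.05 (detected in 5 of 5 and 1 of 10 cells), Pnmal2 by 4.53, the transcription factors Nhlh2 by 4.21 (5 of 5 and 2 of 10) and Tcf4 by 3.19, the axon guidance receptor gene Robo3 by 4.10 and Lhfp by 3.88. Also higher were Lamtor1 by 3.80, Ier5 by 3.04, Jakmip2 by 2.93, Lamp5 by 2.85 and Slc6a9 by 2.59. They had lower Ctxn1 (-4.51, detected in 2 of 5 and 9 of 10 cells), the phospholipase gene Pla2g6 (-4.31), Crym (-4.09), the lactate transporter gene Slc16a3 (-3.97, 0 of 5 and 7 of 10), and Gadd45g (-3.81). Lower too were the retinoic acid binding protein gene Crabp1 (-3.53), Ptpro (-3.34), the potassium channel interacting protein gene Kcnip1 (-3.32), Cdk16 (-3.07), Atrnl1 (-2.93), Gad1 (-2.66) and Ssu72 (-1.81). The X-inactivation transcript Xist had the widest gap, 7.002. Its log2 signal was 14.65 ± 0.43 (SD, 5 cells) in the cultured cells and at the floor of 7.64 in all 10 others, and a Y-linked gene was detected in 7 of those 10 cells and in 0 of the 5 cultured cells. With each cell's median over a gene's probe sets in place of 1 probe set, the difference of Ier5 turned to -0.37, and those of Xist (3.06), Jakmip2 (0.30), Kcnip1 (-1.75), Cdk16 (-0.68), Pla2g6 (-0.00) and Ssu72 (0) were nearer to 0. Without cultured cell D5, Ssu72 was at -2.81. These genes were chosen by the difference of group medians, which was wider than that of means by over 1.5 times for many of them, at 7.22 for Lamp5, 6.51 for Robo3, 6.48 for Ier5, 6.08 for Lhfp, 6.05 for Lamtor1, 6.01 for Slc6a9, 5.89 for Jakmip2, 5.80 for Tcf4, -5.87 for Crabp1, -5.67 for Ssu72, -5.46 for Atrnl1, -5.34 for Kcnip1, -5.20 for Gad1 and -5.03 for Cdk16 and Ptpro.

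The median over all 8570 genes was itself higher by 0.31 in the cultured cells (0.08 after quantile normalization), so each gene list was set against 10000 random lists of matched expression. Of 27 lists, 11 had a median outside the central 95% of the random lists. The housekeeping list, at -0.68 (1 higher, 5 lower, 3.46th percentile, with B2m at -1.56, Actg1 at -1.32 and Eef1a1 at -1.14), was low in the cultured cells too but inside the random range. Genes of growing and immature neurons had a median of -0.79 (3 members higher, 17 lower, 0.07th percentile of the random lists), with the microtubule regulator Stmn2 at -2.46, Nnat at -2.29 and the neuronal tubulin gene Tubb3 at -1.91, against 1.98 for Elavl3. Hypoxia and glycolysis genes had -0.93 (4 higher, 9 lower, 0.07th percentile), with the glycolytic enzyme genes Ldha at -3.18, Pfkl at -2.70 and Aldoa at -1.96, and Pdk1 at 2.14. The rod photoreceptor list had -1.05 with 10 of 10 members lower (0.02nd percentile), among them Pdc at -2.76, Rom1 at -1.80 and Pde6g at -1.78. Muller glia genes had -0.84 (2 higher, 5 lower, 0.58th percentile), with the intermediate filament gene Vim at -3.00 and Car2 at -1.80, and progenitor and cell cycle genes had -0.67 (1 higher, 7 lower, 0.65th percentile). The amacrine transcription factors had a median of -0.50 but a mean of -0.05 (7 higher, 11 lower). Their widest members were Nhlh2 at 4.21, Tcf4 at 3.19, Ebf3 at 3.05 and Meis1 at -2.55. Their median and those of the ribosomal protein list (-0.66) and the immediate early genes (-0.52) were also below the random range. Above it were the ganglion cell list (1.55, 2 of 3 members higher), with the neurofilament genes Nefm at 2.41 and Nefl at 1.55 and Sncg at -0.65, the calcium-binding proteins (1.37, 7 of 7 members higher, Cabp1 at 3.08) and the 2 glycine transporter genes (1.88). Synaptic genes were higher in number but within the random range, with a median of 0.69 for presynaptic genes (16 higher, 2 lower, 84.1st percentile) and 0.79 for postsynaptic receptors (11 higher, 2 lower, 81.6th percentile).

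Several of these positions rested on few cells or on 1 setting. Without cell B3 or B4 of the group with no culture stated the rod median was -0.65 or -0.60, still below the random range, and without cell B4 the progenitor median was -0.44 and that of the amacrine transcription factors -0.23. The Muller glia list was inside the random range without cell A6, B4, D5, D3 or C1 (medians from -0.64 to -0.44), and the ganglion cell list without D5 (0.93) or D3 (1.02). The calcium-binding list was inside the range without any of A7, A1, D5, D3 or D6 (0.92 to 1.42), the ribosomal list without A6, B1, B3 or D5 (-0.61 to -0.53), and the glycine transport and immediate early lists each without 11 of the 15 cells in turn. Of 8 other settings, the glycine transport list stayed outside the random range in 2, the calcium-binding and immediate early lists in 3 each, the ribosomal list in 4, and the amacrine transcription factors and the progenitor list in 5 each. The calcium-binding list was inside it with floors of 0.1 (1.75) and 1 (0.75) times the trimmed mean, after quantile normalization (0.90), among genes detected in at least 5 cells (1.61) and with group medians (1.15). The glycine transport list was inside it with both floors (2.497 and 1.30), after scaling to the 75th percentile (1.75), with the median over probe sets (1.56), and without a detection filter or with detection in at least 5 cells (1.88 each). With group medians in place of means, the rod, Muller glia, progenitor, ganglion cell, amacrine transcription factor and immediate early lists all had a median of 0. The count of 11 lists was 7 without cultured cell D5 or D3, 7 among genes detected in at least 5 cells and 5 with group medians. Fewer lists entered with detection in at least 5 cells, and the ganglion cell list was not among them. After quantile normalization the ribosomal median was 0.15 and the immature neuron median -0.19, and with the median over probe sets the immature neuron median was -0.31. With no detection filter the rod median was -0.36, that of Muller glia -0.37 and that of the progenitor list -0.29, all still below the random range.

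**Figure D3:**
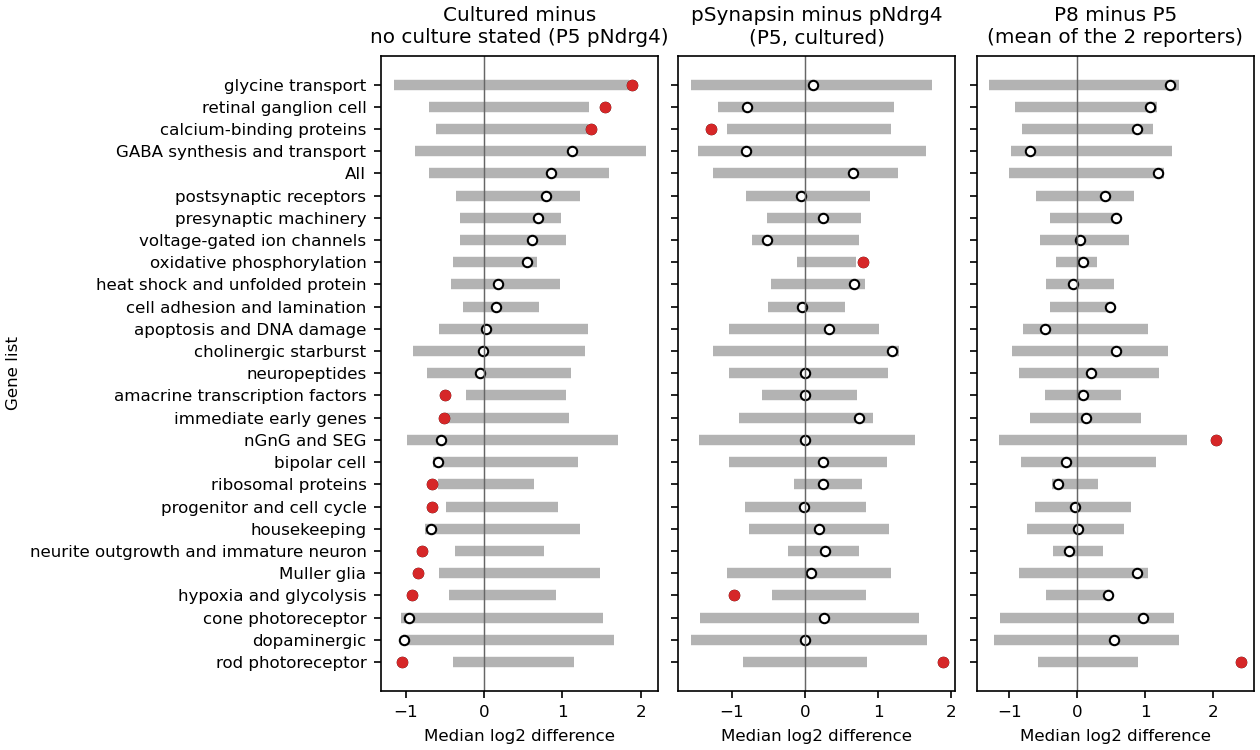
Median log2 difference of each gene list (horizontal axis, log2 units) for the culture, reporter and age comparisons, with the central 95% of 10000 matched random lists as a bar. The rod photoreceptor list lies below the random range for culture (-1.05) and above it for the reporter (1.88) and for age (2.42), and the same 5 cultured P5 pNdrg4 cells enter all 3 comparisons.

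The reporter comparison set the 4 P5 pSynapsin cells against the 5 cultured P5 pNdrg4 cells, with 2 against 2 cells at P8 as a separate value. At P5 the pSynapsin cells had higher Pcp4, a calmodulin regulator, by 5.17 (4 of 4 and 1 of 5 cells, 3.87 at P8) and Hmgcs1, an enzyme of cholesterol synthesis, by 5.12 (1.59 at P8). Snx17 was higher by 4.74 (-1.04 at P8), Ly6h by 4.49 (0.09), Txndc15 by 4.03 (1.46), the acid-sensing channel gene Asic1 by 3.80 (0.75), the cadherin gene Cdh22 by 3.70 (0.51), Loxl1 by 3.49 (3.02), the GABA receptor subunit gene Gabrb2 by 3.32 (0.31), Ptpro by 3.16 (0.33), Tmem215 by 2.34 (1.11) and Pkig by 2.09 (2.01). Lower were Xist (-5.84, -6.87 at P8), the vesicle protein gene Rph3a (-5.23, detected in 0 of 4 and 5 of 5 cells, but 4.82 at P8), Saraf (-4.46, 1.83 at P8), the reelin receptor gene Vldlr (-4.43, -4.94 at P8), Ier5 (-3.99, -2.16 at P8), Tunar (-3.76, 0 at P8), Srsf12 (-3.75, 4.01 at P8), Spock1 (-3.66, 0 at P8), Lrpap1 (-3.12, -0.31 at P8) and Klhl17 (-2.90, -0.58 at P8). Tfap2b (-3.55, -2.07 at P8) and Tfap2a (-3.10, but 0.23 at P8) were lower at P5, with neither detected in cells E1, E3 and E4 and both in E2. Without E2 the differences of Gabrb2 and Tmem215 were 5.03 and 3.83, without E4 that of Pkig was 3.63, and with the median over probe sets Vldlr was at -0.83, Xist at -3.06, and Ier5 and Tmem215 at 0. The difference of group medians, by which these genes were chosen, was over 1.5 times that of means for Ly6h (6.93), Gabrb2 (6.80), Cdh22 (6.51), Txndc15 (6.41), Asic1 (5.97), Ptpro (5.79), Loxl1 (5.74), Pkig (5.68), Tmem215 (5.66), Tfap2b (-5.81), Spock1 (-5.50), Tfap2a (-5.37), Klhl17 (-5.31) and Lrpap1 (-5.27). Sex-linked genes went with the reporter at both ages: Xist was detected in 5 of 5 pNdrg4 and 1 of 4 pSynapsin cells at P5 and in 2 of 2 and 0 of 2 at P8, and a Y-linked gene in 2 of 4 pSynapsin cells at P5 and 2 of 2 at P8 but in no pNdrg4 cell of this comparison.

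Of the 27 lists, 4 lay outside the random range in the reporter comparison. Oxidative phosphorylation genes were higher in pSynapsin cells (median 0.79, 20 higher, 3 lower, 99.1st percentile, and 0.55 at P8 at the 92.7th percentile). Hypoxia and glycolysis genes were lower (-0.97, 4 higher, 9 lower, 0.04th percentile) at P5 and higher at P8 (1.07, 99.3rd percentile). Calcium-binding protein genes were lower (-1.28, 0 higher, 7 lower, 1st percentile), with Necab1 at -2.83 and Vsnl1 at -1.74, and at P8 the list was at -0.71 (14.7th percentile). The rod photoreceptor list was higher at P5 (1.88, 8 higher, 0 lower, 99.99th percentile), with Sag at 3.36 and Rom1 at 2.62, and at P8 it was at -0.74 (9.70th percentile). Without E2 the rod median was 0.79 and inside the random range. Without pNdrg4 cell D6 the hypoxia and glycolysis median was -0.40 and inside the range, and without E4 it was -0.56. The calcium-binding list was inside it without D3 (-0.89) or E3 (-1.21), among genes detected in at least 5 cells (-1.29) and with group medians (-1.15), and oxidative phosphorylation was inside it after quantile normalization (0.50) or with group medians (0.55). Scaling to the 75th percentile moved the median of all genes from 0 to 0.13. It moved the hypoxia and glycolysis median from -0.97 to -0.65, still below the random range. Across 8570 genes, which are not independent replicates, the P5 and P8 reporter differences had a Pearson r of 0.03 and a Spearman rho of 0.04, and 52.4% of the 7368 genes with a difference in both had the same sign.

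The age comparison set P8 against P5 cultured cells within each reporter, 2 against 5 with pNdrg4 and 2 against 4 with pSynapsin, and took the mean of both differences. The P8 cells came from retinas cultured for 8 days and the P5 cells from retinas cultured for 5, so age and length of culture were not separate, and the pNdrg4 cells at P5 were those of the other comparisons. Higher at P8 were the glutamate and cysteine transporter gene Slc1a1 by 4.69 (3.64 with pNdrg4, 5.74 with pSynapsin), the catalase gene Cat by 4.62 (4.31 and 4.93), Rnf152 by 4.33, Hspa12a by 3.96, Olfm1 by 3.87, Abhd14a by 3.71, Cplx1, a regulator of synaptic vesicle fusion, by 3.48 (3.40 and 3.56), Sec16a by 3.35, the serine synthesis gene Psat1 by 3.28, and Map3k9 by 3.23. So were Cend1 by 3.12 and the proton pump subunit gene Atp6v1c1 by 3.05. Lower at P8 were the noncoding RNA gene Snhg5 (-4.31, with -5.15 and -3.47), Gsto1 (-4.15, with -3.93 and -4.37), Fundc2 (-3.65), Phf3 (-3.62), Ndufa10 (-3.48), Mrpl24 (-3.30), Rprd1a (-3.29), Cers5 (-3.10), Dpy30 (-2.92), Sh3glb1 (-2.73), Mbtps1 (-2.68) and the histone methyltransferase gene Ezh2 (-2.58). These genes were chosen for having the same sign in both reporters. With the median over probe sets, Fundc2 turned to 0.08, Slc1a1, Map3k9 and Phf3 were at 0, Snhg5 at -0.04, Hspa12a at 0.15, Rprd1a at -0.48, Mbtps1 at -0.57 and Sh3glb1 at -1.29. Without P8 pNdrg4 cell A1, Dpy30 was at -1.65 and Sh3glb1 at -1.62, without P8 pSynapsin cell B3 Dpy30 was at -1.85, and without P8 pSynapsin cell B4 Sh3glb1 was at -1.52. With floors of 0.1 and 1 times the trimmed mean, Phf3 was at -5.62 and -2.36 and Ezh2 at -3.91 and -1.72, and with a floor of 1 Map3k9 was at 2.07 and Rprd1a at -2.16.

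In the age comparison 2 of 27 lists lay outside the random range. The rod photoreceptor list was higher at P8 (median 2.42, 10 of 10 members higher, 100th percentile), at 3.20 with pNdrg4 and 1.29 with pSynapsin, with Rcvrn, the photoreceptor calcium sensor, at 3.68, Pde6g at 2.94, Pdc at 2.56 and Sag at 2.56. Without P8 pSynapsin cell B4 its median was 1.11 and still above the random range. The list of nGnG and SEG amacrine cells, which joins cells that use neither GABA nor glycine with a glycinergic class, had a median of 2.04 (3 of 3 members higher, 99.5th percentile), with Ppp1r17 at 2.73, Neurod2 at 2.04 and Ebf3 at 0.17. This list was at 3.13 with pNdrg4 (2 higher, 1 lower, 99.8th percentile) but at 0.74 with pSynapsin (3 higher, 74.6th percentile). It was inside the range without P8 pNdrg4 cell A1 (1.17) or P8 pSynapsin cell B4 (1.04), with the median over probe sets (0.07) and among genes detected in at least 5 cells (1.11). It was still above the range, with a smaller median, without a detection filter (1.11) and with a floor of 1 times the trimmed mean (1.30). AII genes (1.19, 5 of 5 higher, 96.2nd percentile) and presynaptic genes (0.57, 13 higher, 5 lower, 96.5th percentile) were just inside it, as were the ganglion cell list (1.07, 96.1st percentile) and the glycine transporter genes (1.37, 96.3rd percentile). So were cell adhesion genes (0.49, 96.1st percentile) and hypoxia and glycolysis genes (0.45, 96.7th percentile), the latter at -0.004 with pNdrg4 and 1.23 with pSynapsin. The count of 2 lists was 1 without P8 pNdrg4 cell A1, 4 without C6, D5, E1, E2 or P8 pSynapsin cell B4, 5 without D3 or D6, and 6 without P8 pSynapsin cell B3. Ribosomal proteins had a median of -0.28, GABA genes -0.69, immature neuron genes -0.12 and heat shock genes -0.06. Across 8570 genes, which are not independent replicates, the age differences of both reporters had a Pearson r of 0.04 and a Spearman rho of 0.04, and 51.2% of 7540 genes had the same sign. Over the 3 comparisons, 17 list medians lay outside the range of the random lists. The comparisons share the 5 cultured P5 pNdrg4 cells, some lists share genes, and random lists lack the co-detection of real ones, so this count has no chance rate to be set against.

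The E19 cell and the P4 cells were too few for more than values. The E19 cell and P4 cells A3 and B4 each had Gad1, Tfap2a and Tfap2b and none had Slc6a9. Lhx9, a homeodomain factor of developing neurons, was detected in P4 cell A3 and in cells A7 and A1 with no culture stated, all 3 of which had Gad1. The vesicular monoamine transporter gene Slc18a2 was detected in the E19 cell and P4 cell A3 and in no other cell. No rod list gene was detected in the E19 cell, and the P4 cells had 0 and 1.

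The last question was which genes marked the same cells as a class marker. Slc6a9 was best matched by Dab1, a reelin adaptor (phi 0.77, 12 shared cells), Ube2a (0.77), Naa35 (0.73), Ado (0.73) and Camkv (0.70). Gad1 was best matched by Kcnip1 (phi 0.77, 10 shared cells), the GABA transporter gene Slc6a11 (0.69, 8 shared cells), Lingo1 (0.69), Rai14 (0.64) and Git1 (0.64), and Lamp5 and Lhfp were as far apart from it as Slc6a9 was (phi -0.77). Calb2, the calretinin gene, was best matched by Kbtbd11 (phi 0.69), Pik3r3 and Rheb (0.67 each), Slc6a5 (0.67, with 5 of 5 Slc6a5 cells) and Thap11 (0.66), and Gad2 by Tipin (0.57), Zcchc12, Jam3, Cbln2 and Slc22a23 (0.56 each). Genes detected in as many cells as the marker had a median best phi of 0.70 for Slc6a9, 0.71 for Gad1, 0.70 for Gad2 and 0.75 for Calb2, so the partners of Slc6a9, Gad1 and Calb2 lay within what other genes reached with 26 cells. Gad2 had a weaker best partner than most, and 0.830% of genes detected in as many cells had a lower best phi.

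Other genes were bright in 3 to 13 cells and near background in the rest. Reln, which encodes the extracellular signal reelin, had a median signal of 26350 in 5 cells and 20.6 in the others. The neural transcription factor gene Pou3f3 was detected in 5 cells and its neighbour Pantr1 in 4, and P4 cell B4 and cells A2, A5 and B2 with no culture stated had both. The remaining genes of this kind included Lhx9 (3 cells), Gjd2 (5), Plagl1 (6), Ly6h (9), Robo3 (5), Gabrb2 (8), Tmem215 (7), Pcp4 (10), Nr4a2 (5), Cbln1 (6), Sox2 (4), Zfp503 (3), Pdpn (3), Dact2 (4), Cdh22 (10), Ppp1r17 (3), Virma (3), Shkbp1 (3), Zfhx3 (3), Marf1 (5) and Loxl1 (5). Ly6h, Gabrb2, Cdh22 and Tmem215 were all detected in P5 pSynapsin cells E1, E3 and E4, P8 pNdrg4 cell A2 and P8 pSynapsin cell B3.

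Genes of other retinal cell types were measured beside these. Of the rod photoreceptor genes, Crx was detected in 14 cells, Rom1 in 13, Sag in 12, Pdc in 11, Nrl in 10, Pde6g in 7, Rcvrn in 5, Pde6b in 4 and Gnat1 and Rp1 in 2 each, while Prph2, Gngt1 and Pde6a were not detected. Per cell, 0 to 7 of these genes were detected with no culture stated, 0 to 2 in the cultured P5 pNdrg4 cells, 1 to 8 in the P5 pSynapsin cells, 7 and 9 in the P8 pNdrg4 cells and 10 and 3 in the P8 pSynapsin cells. Otx2, a photoreceptor and bipolar cell factor, was detected in cells B2, B3 and B4 with no culture stated. Cell B4 of that group also had the proliferation gene Mki67 at a signal of 19685, Cdk1, Rrm2, Hes5 and Top2a, and neither Tfap2a nor Tfap2b. Glial genes were mixed, with Glul in 18 cells, Dkk3 in 16, Car2 in 14, Vim in 11, Clu in 7, Rlbp1 in 5, Cp in 4 and Apoe and Aqp4 in none. None of the 7 microglia genes or the 6 pigment epithelium genes was detected, and horizontal cell genes were limited to Onecut2 (4 cells). The lens gene Crybb1 reached 44364 in cell A8 with no culture stated and was detected in no other cell, and of the vascular genes Kdr was detected in 5 cells.

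**Figure D4:**
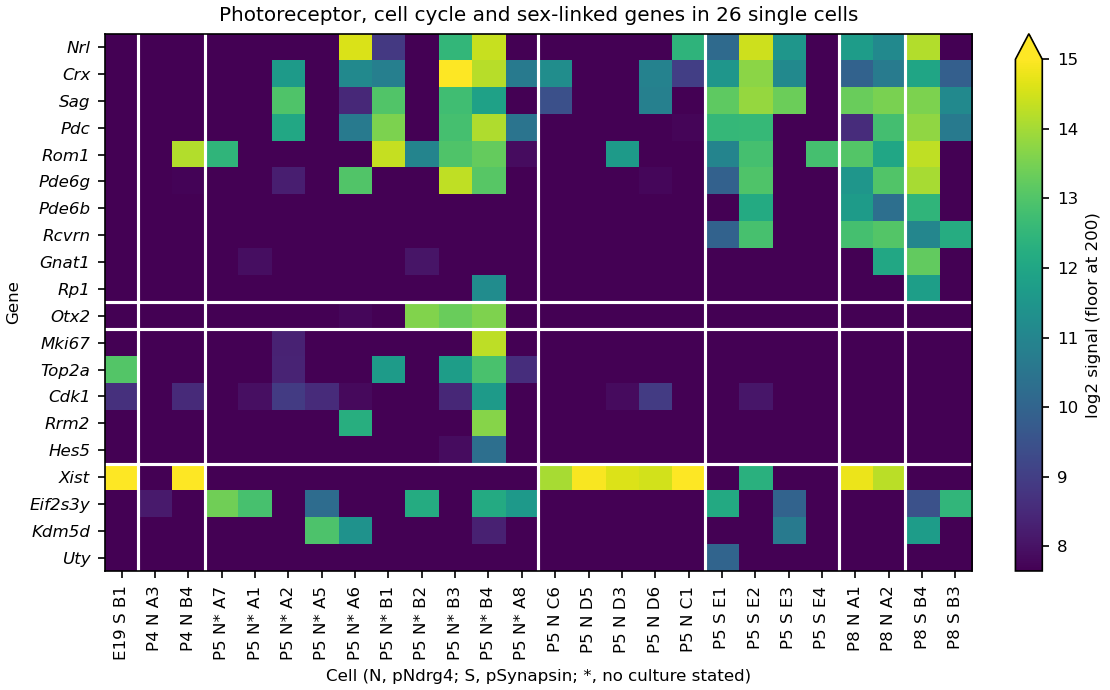
Signal of photoreceptor, cell cycle and sex-linked genes (colour, log2 scale, with the floor of 200 as the lowest value) in each of the 26 cells, ordered by group along the horizontal axis, with 1 line per gene. P8 pSynapsin cell B4 has 10 of the rod genes, P8 pNdrg4 cell A2 has 9 and P5 pSynapsin cell E2 has 8, and Xist is detected in 10 cells that have no Y-linked gene.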

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

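Of the tests below, the comparison of shared genes between culture groups and that of Y-linked genes were fixed before their results were seen; the 2 tests of rod genes together, the share of signal in the brightest probe sets and the count of cultured cells without Xist were chosen after the results were seen.

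Rod photoreceptor genes were detected in cells labelled amacrine, up to 10 in 1 cell. A candidate source is RNA of photoreceptors or their precursors in the same tube. If so, the rod genes would occur in the same cells. Their mean pairwise phi of 0.44 (0.4388) lay at the 100th percentile of 10000 random lists of genes detected in as many cells, above the highest of these (0.247). That argues against cells with more genes simply having more of everything. Expression of these genes together by the picked cells themselves would give the same outcome, so the test cannot tell these sources apart. The random lists were not matched on group, while the rod list differed between groups. Of the abundant rod genes, Sag, Pdc, Rom1 and Pde6g had median signals of 8711, 6102, 7291 and 8170 where detected, but Prph2 (at most 24.3) and Gngt1 (at most 252) stayed below detection in all 26 cells, which argues against mature rods unless those probe sets fail. None of the 13 measured rod genes is in another of the lists. Whether hand-picking of fluorescent cells kept out photoreceptor RNA was not tested. Expression of these genes by the amacrine cells themselves was not tested and stays open.

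The P5 pNdrg4 cells with no culture stated had fewer detected genes (median 2361.5) than the cultured ones (3256). Transcripts lost in amplification cannot be told apart from a difference that goes with culture: of 646 genes detected in all 8 P5 pSynapsin and P8 cells, a median of 88.1% was detected in the cultured cells (87.0 to 94.1) and 74.1% in the others (64.7 to 85.1), 13.9 percentage points (13.9319) apart with no overlap, but those genes were chosen in cultured cells, so either would give this outcome. A few probe sets taking most of the signal cannot be told apart from the rest: the 100 brightest took a median of 13.7% of the signal (10.8 to 17.1) against 9.12% (6.32 to 11.8), 4.58 points (4.5752) apart with overlapping ranges. A biological difference that goes with culture was not tested and stays open, since culture, retina, day and the mix of Gad1 and Slc6a9 cells are confounded here.

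Xist was detected in all 5 cultured P5 pNdrg4 cells and in none of the 10 with no culture stated. A response of Xist to culture in every cell is argued against by 6 of the 16 cultured cells, which lacked Xist. Among these 6, a Y-linked gene was detected in 2 P5 and 2 P8 pSynapsin cells. A response confined to cells without Y-linked genes therefore stays open. Retinas of different sex could account for the Xist pattern. A Y-linked gene was detected in 68.8% (68.75) of the 16 cells without Xist, 11 cells, and in 0 of the 10 cells with it. The share stayed under the 80% set as the bound, and 5 cells had neither, so the test as set did not decide. A cell with neither may have lost the transcript, so that share cannot exclude different sex. Of the 10 cells with no culture stated, 7 had a Y-linked gene and 0 had Xist. Of the 5 cultured P5 pNdrg4 cells, 5 had Xist and 0 had a Y-linked gene. These values argue against 1 shared sex in the 2 groups, although cells with neither stay unassigned. Where sex differs, sex, culture and retina stand together in that comparison. Sex would also stand with the reporter in the other, where Xist was detected in 7 of 7 pNdrg4 and 1 of 6 pSynapsin cells at P5 and P8.

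Some cells lay far from the others of their group on Dixon's criterion, which chance meets in about 1 of 20 groups of normally spread values. That rate does not apply here, because a single cell above the floor meets the criterion by construction and the named genes were picked for wide differences. It was met in 19 of 84 combinations of a measure and a group, in 6 of these with all other cells at the floor, and in 63 of 207 combinations of a named gene and a group, in 30 of these with all other cells at the floor. Among the P5 pNdrg4 cells with no culture stated, cell B4 had 3513 genes detected (others 1909 to 2610) and a mean log2 signal of progenitor and cell cycle genes of 11.90 (others 7.87 to 9.26), cell B1 an AII list mean of 11.36 (7.64 to 9.05), and cell A8 a ganglion cell list mean of 9.81 (others at the floor of 7.64). Among the cultured P5 pNdrg4 cells, cell D6 had a starburst list mean of 8.95, an immediate early gene mean of 9.98 (7.68 to 8.27) and a hypoxia and glycolysis mean of 13.44 (10.94 to 11.52), cell C6 an ion channel mean of 10.68 (8.66 to 9.24) and an apoptosis list mean of 9.40 (8.84 to 8.96), and cell C1 a cone list mean of 9.59. Among the P5 pSynapsin cells, E2 had an AII mean of 12.48 (8.77 to 9.24), a neuropeptide mean of 7.77, a cone mean of 10.25, a bipolar mean of 9.82, a ganglion cell mean of 8.64, a Muller glia mean of 10.86 (8.39 to 8.79), an immediate early gene mean of 10.86 (8.25 to 8.60) and an immature neuron mean of 11.87 (12.32 to 12.37), and E1 a glycine transport mean of 9.31 (10.80 to 10.91).

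Rph3a differed in opposite directions in every cell: pSynapsin against pNdrg4 was -5.23 at P5 and 4.82 at P8, a gap of -10.05, and the same gap of -10.05 separates the age differences of both reporters. The difference was not tested, and it was found among 194 comparisons of this kind. Of 9160 probe sets with no gene name, which no comparison used, 30 were detected in all 26 cells and 2245 in at least 1.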

How the results depend on the processing

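Leaving out cell B4 of the group with no culture stated was chosen after the data were seen; the other alternatives were planned. Under the other settings, 164 values that answer a comparison stayed within a bound, 25 moved past it and 1 changed sign. Of all other values, 1085 stayed, 96 moved and 2 changed sign. The bound was the SD over cells for list and gene differences and for genes detected. For phi it was the SD over genes, for shares of cells the counting interval, and for the rest a fixed factor or step. The SD over cells is wide, so a value that stayed need not be stable. With group medians the rod, Muller glia, progenitor and immediate early medians (culture) went to 0 and counted as staying. The cause of a move was not tested. Detection at 1 and 4 times the trimmed mean gave 3748 and 2616 genes in the cultured P5 pNdrg4 cells and 4011 and 2718 in the P5 pSynapsin cells (3668 with the highest probe set per cell). At 1 times, the best phi was 0.85 for Slc6a9 and 0.75 for Gad2, and that of Gad1 with Slc6a9 was -0.84; at 4 times, the best phi was 0.66 for Gad2 and 0.80 for Calb2.

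In the culture comparison, quantile normalization turned the ribosomal median to 0.15 and moved that of immature neuron genes to -0.19. The amacrine transcription factors were at -0.99 with a floor of 0.1 times the trimmed mean, -0.038 with the median over probe sets, -0.033 with no detection filter and 0 with group medians, and the ganglion cell list was at 0 with no detection filter and with group medians. The median over probe sets also turned Ier5 to -0.37, turned Fundc2 (age) to 0.079 and brought the nGnG and SEG list (age) to 0.069. Quantile normalization gave 0.50 for oxidative phosphorylation in the reporter comparison. Of 27 lists, or fewer with detection in at least 5 cells, those outside the random range numbered 7 (detection in at least 5 cells) and 5 (group medians) for culture and 2 (group medians) for the reporter. For age they numbered 4 with a floor of 1, with detection in at least 5 cells and with group medians. With detection in at least 5 cells the ganglion cell list, among others, kept too few members to enter.

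Leaving out 1 cell at a time gave 7 to 12 lists for culture, 3 to 6 for the reporter and 1 to 6 for age. Without cell B4 with no culture stated, the best phi was 0.84 for Slc6a9 and the mean phi of the rod genes 0.47. The immature neuron and hypoxia lists (culture) lay outside the random range in 8 of 8 settings and 15 of 15 leave-one-out runs, although the immature neuron median shrank to -0.19 after quantile normalization and to -0.31 with the median over probe sets, and the rod list (age) in 8 of 8 and 13 of 13. No paired analysis was possible because replicate numbers only count cells within a group and no test was made. Signals near background limit the differences too, since values at the floor have no order and a difference against them is understated.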

Other observations

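The genes given here were picked after their values were seen. Several list genes were detected in every cell: Tuba1a, Tubb2a, Tubb2b, Stmn1, Crmp1, Marcks, Marcksl1 and Sox4 were each detected in 26 of 26 cells, as were the actin genes Actb and Actg1, the elongation factor gene Eef1a1 and the chaperone genes Hspa8, Hsp90aa1 and Calr. Genes of the presynaptic list ranged widely, with Snap25 and Vamp2 in 25 cells, Syt1 in 24, Syt4 in 23 and Rab3a in 22, Bsn in 14, Syp in 13, Cplx1 in 10, Stx1a and Rims1 in 6 each and Syn2 in 3, while Sv2b and Vamp1 were detected in 1 cell each. Among glutamate receptor genes, Gria2 and Gria4 were detected in 21 cells each and Gria3 in 19, against 9 for Gria1 and 0 for Grin2a, and the glycine receptor subunit gene Glra2 in 13 against 0 for Glra1.

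Class genes also met in pairs outside the comparisons. Ebf1 (7 cells), Ebf3 (8 cells) and Neurod2 (6 cells) shared no cell with Gad1, while Lhx9 (3 cells) and Cartpt (2 cells) were detected in Gad1 cells alone. These pairs followed the groups in part. Of the 10 cells with no culture stated, 7 had Gad1, and Ebf1 was detected in 0, Ebf3 in 1 and Neurod2 in 2. Lhx9 and Cartpt were detected only in P4 cells and cells with no culture stated. Pairing by class was therefore not separate from group. Of the immediate early genes, Jund was detected in 13 cells, Btg2 in 8, Jun in 5, Dusp1 in 4, Fos and Ier2 in 2 each and Fosl2 and Egr1 in 1 each, and Fosb, Junb, Egr2, Egr3, Nr4a1, Arc and Atf3 were detected in no cell.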
